A study of Solanum lycopersicum with 5 samples.

How the data were processed

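RNA was extracted from leaves of the Indian tomato (Solanum lycopersicum) cultivar Pusa Ruby, and 5 polyadenylated RNA libraries were sequenced as paired ends on an Illumina NextSeq instrument, per the labels' protocols. Plants were grown at 25 °C and 70% humidity with 16 h of light and 8 h of darkness. The libraries came from 1 untreated wild type sample, 2 untreated samples of plants overexpressing the microRNA miR6024 (called OVX6024), and 1 infected sample of each genotype. Infected leaves of plants aged 1.5 months had received drops of a suspension of spores and mycelia of the early blight fungus Alternaria solani at 1000000 CFU per ml, and were harvested 48 h later. For the untreated samples plant age and harvest time are not given, and no sample is labelled as mock-inoculated. The labels do not say whether the 2 untreated OVX6024 samples came from separate plants or transgenic lines. The spread between them, on which p-values rest in whole or in part, may therefore be technical.

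The authors deposited a table of raw read counts per transcript for all 5 libraries. Its values, as deposited, were treated as estimated counts: between 234 and 299 of the 35215 values per library are fractions, whose origin is not given in the sources used here, and all others are whole. They were rounded to whole numbers here. The authors also deposited an FPKM table per sample, which lists only values above 0. TopHat2, Cufflinks and Cuffdiff are named in the submitters' processing notes. Their versions and roles, the program that counted the reads, the genome build and the strand setting are not given in the sources used here. The FPKM values of a library divided by its counts were nearly the same for each transcript in all libraries, apart from 1 factor per library. That factor was not the total count, so the FPKM values carried a further scaling between libraries. FPKM served only to match files to count columns, as an alternative scaling, and to recover each transcript's relative length.

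The table holds 33809 Solyc locus identifiers and 1406 identifiers of non-coding RNA. The files do not pair identifiers with names, and 0 of them matched the 41476 genes of the reference table. Gene names and functions were therefore not used. The 21 gene lists fixed as patterns on gene descriptions, and the list of predicted miR6024 targets, which needs transcript sequences, were not analysed here. The chromosome of a locus is the one its Solyc identifier carries, and loci were ordered along a chromosome by the number in the identifier, following the tomato naming convention. The reference table has 1 entry for the miR6024 precursor, but no row of the count table could be matched to it, so the overexpression itself was not checked here.

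The names of the 2 infected libraries conflict. Count columns were assigned to samples by their names, which match the sample titles. The FPKM file attached to the sample titled infected wild type, however, is named for infected OVX6024 and holds the values of the count column of that name. The reverse holds for the other file. The names and values of the FPKM files thus match the count columns, and the conflict lies in the samples the files are attached to. Comparisons that do not depend on which infected library is which genotype were made the main ones, and the others were also computed with the 2 labels exchanged in their main setting. The OVX6024 libraries alone, the left-out libraries and the other alternatives were run with the names as given only.

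Transcripts with at least 1 CPM (counts scaled to a common library size) in at least 2 libraries were tested (18094). Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Standard errors of log2 fold changes were computed as the fold change divided by the square root of F. The infection effect was fitted with infection alone, leaving 3 residual degrees of freedom. Its spread therefore includes differences between the genotypes among untreated and among infected libraries. The difference of the 2 untreated OVX6024 libraries from the untreated wild type library was a contrast in a model of 4 groups. That model has 1 residual degree of freedom, from the OVX6024 pair, and the lone wild type library is assumed to vary like that pair. The genotype effect over both states was fitted with infection as covariate (2 residual degrees of freedom). The interaction came from the model of 4 groups. Single libraries were compared without a test, by counting transcripts with a ratio of at least 4 on the log2 CPM scale (prior count 2) and at least 10 CPM in the higher library.

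On data simulated for the infection comparison (18094 transcripts), the test recovered 22% of transcripts changed 2-fold, 90% of those changed 4-fold, 98% of those changed 8-fold and 92% of those changed 16-fold, and called 16 unchanged ones. On data simulated for the untreated genotype comparison, the recovered shares were 2%, 46%, 86% and 88% for the same folds, with 15 unchanged transcripts called. For the genotype effect over both states they were 8%, 80%, 90% and 96%, with 15 unchanged transcripts called, and for the interaction 0%, 10%, 40% and 76%, with 26. The simulated spread came from the model of 4 groups and held no other differences between groups. The shares for the infection effect and for the genotype effect over both states may therefore be too high. The simulated spread also comes from the untreated OVX6024 pair and was given to every library. If that spread is technical, all of these shares may be too high and the numbers of unchanged transcripts called too low. The analysis of neighbouring loci was also tested on simulated data with planted runs.

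Total counts per library ranged from 10842804 to 19636281. A count of 0 allows a level of up to 3 counts, which is 0.153 to 0.277 CPM of a library's total. Intervals and floors cover counting error only, since reads are not independent molecules. Where a group had 0 counts, folds were computed against 3 counts over the whole group and are given as lower bounds.

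Transcripts were named by a rule set before the data were examined: among those past the threshold, with a mean of at least 5 CPM over the 5 libraries and no overlap between the compared libraries, the largest changes each way, and for the single infected libraries the largest ratios each way at 20 CPM or more. The rule also asked for a gene name. As none could be matched, that condition was dropped and only the first 2 identifiers each way are given. The alternatives tried were DESeq2 1.42.0 and its size factors, other filters, a minimum fold of 2, covariates, left-out libraries and exchanged labels of the infected libraries. Chosen after seeing the data were total counts and the FPKM scale as scalings, the OVX6024 libraries alone, the overlaps of calls without shared libraries or untreated wild type, and the analyses of chromosomes (limma 3.58.1, camera), neighbouring loci, abundance classes and non-coding RNA. Neighbouring loci were compared over 11806 pairs of adjacent tested loci without fractional counts, with 1000 permutations of loci within chromosomes. Runs are stretches of at least 4 adjacent loci called in the same direction.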

Results

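Leaf transcriptomes of wild type and miR6024-overexpressing tomato were profiled without infection and 48 h after inoculation with Alternaria solani, a necrotrophic fungus that causes early blight. miR6024 is a plant microRNA known to act on transcripts of NLR immune receptors. The 5 libraries held 14835768 counts (untreated wild type), 10842804 and 14061958 (untreated OVX6024 replicates 1 and 2), 16006545 (infected wild type) and 19636281 (infected OVX6024), and between 20025 and 21623 transcripts had a count. The 100 most counted transcripts of each library took 36.3% of the counts in untreated wild type, 18.4% and 19.8% in the untreated OVX6024 libraries, and 26.5% and 25.6% in infected wild type and infected OVX6024. Identifiers of non-coding RNA took 0.0992% of the counts in untreated wild type (exact 95% interval 0.0976 to 0.101%), 0.0545% and 0.0436% in untreated OVX6024, and 0.172% and 0.202% in the infected libraries.

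The genotype of the 2 infected libraries carries a conflict in the deposited data. The FPKM file attached to the sample titled infected wild type, but named for infected OVX6024, listed 18124 transcripts. All but 0 of these had counts in the column named infected OVX6024, whereas 446 had 0 counts in the column named infected wild type. The FPKM value per count varied between transcripts by an interquartile range of 0.0187 on the log2 scale against the first column and of 1.32 against the second. In what follows the infected libraries carry the names of the count columns, and the comparisons that depend on them were also computed with the names exchanged, though not under each alternative setting.

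The first principal component of log2 CPM, with 75.1% of the variance, separated infected from untreated leaves. The untreated OVX6024 libraries lay on it between untreated wild type and the infected libraries. The correlation across transcripts was 0.96 between the OVX6024 replicates, 0.86 between either of them and untreated wild type, and 0.88 between the infected libraries. It was 0.49 between untreated wild type and either infected library, and 0.68 to 0.70 between an untreated OVX6024 library and an infected one. Transcripts are not independent replicates.

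**Figure D1:**
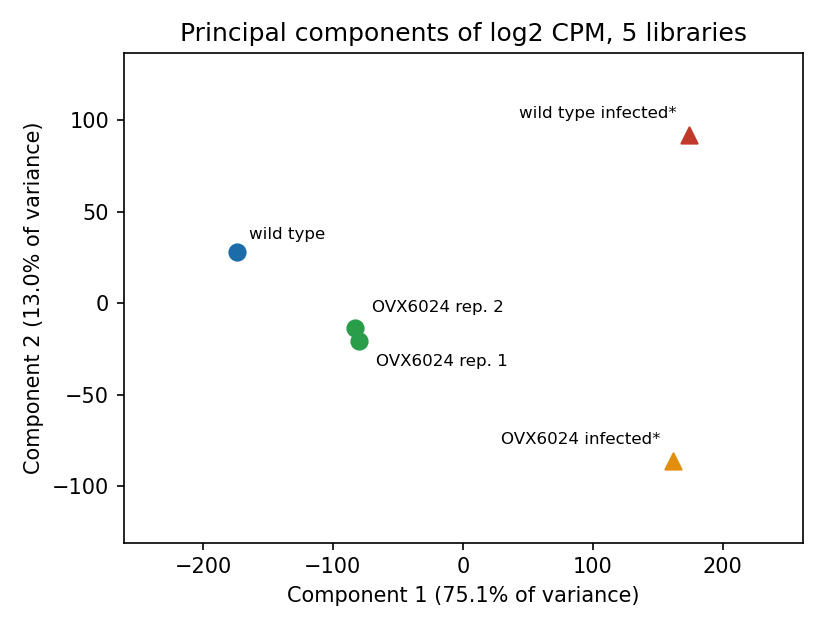
Each point is 1 library, placed by the first 2 principal components of log2 CPM over 18094 transcripts, with circles for untreated and triangles for infected leaves. The untreated OVX6024 libraries lie between untreated wild type and the infected libraries on component 1 (75.1% of the variance), and the asterisks mark the libraries whose genotype names conflict.

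The infection comparison asks which transcripts differed between the 2 infected and the 3 untreated libraries, whatever the genotype. After infection 1599 transcripts were higher and 1989 lower, 19.8% of the 18094 tested (edgeR quasi-likelihood test, adjusted p under 0.05). All 1599 and 1989 changed at least 2-fold and had both infected libraries beyond all 3 untreated ones. Over all tested transcripts 57.2% were separated in this way, against 20% by chance. Of transcripts silent before infection, 46 had 0 counts in the 3 untreated libraries and at least 1 CPM in both infected ones, and their median rise was at least 112-fold. Conversely, 96 transcripts with at least 1 CPM in every untreated library had 0 counts in both infected ones, with a median fall of at least 53.6-fold.

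Among single transcripts, Solyc02g080840.1.1, on chromosome 2, was not counted in untreated leaves and reached 65.3 CPM in infected wild type and 38.8 CPM in infected OVX6024. This is a rise of at least 765-fold (edgeR adjusted p = 0.0118). Solyc02g071490.2.1, also on chromosome 2, rose from 0 counts to 146.5 CPM in infected wild type but to only 4.19 CPM in infected OVX6024 (edgeR adjusted p = 0.0407). Its call was lost when any 1 of the untreated libraries was left out, with edgeR adjusted p of 0.0507 to 0.0718. Over its edgeR alternatives the adjusted p was 0.0146 to 0.0718, and by the DESeq2 Wald test 0.00239. Neither transcript could be tested with either infected library left out, since it then missed the filter. On chromosome 9, Solyc09g084490.2.1 fell from 57.0 ± 22.4 CPM (SD, n = 3) and Solyc09g089540.2.1 from 49.1 ± 12.99 CPM (SD, n = 3) to 0 counts in both infected libraries. These falls were at least 583-fold and 502-fold (edgeR adjusted p = 0.0113 for both).

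The number of called transcripts depended on single libraries. Without infected wild type, 340 were higher and 137 lower, and without infected OVX6024 1022 and 482. Without untreated OVX6024 replicate 1 or 2, the counts were 683 and 1084 or 659 and 1175. The log2 change of the median transcript was -0.11 with TMM, -0.02 with DESeq2 size factors, -0.41 with the FPKM scale and -0.47 with total counts, and changes are relative to these medians. Of the calls, 44.6% were rises with TMM, 31.4% with the FPKM scale and 26.1% with total counts.

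Loci called after infection lay on all 12 chromosomes. Between 18.2% (chromosome 12) and 22.9% (chromosome 5) of the tested loci of each of the 12 chromosomes were called after infection, and camera with a preset correlation, which tests for a shift in 1 direction, called no chromosome (lowest adjusted p = 0.999, and 0.998 with an estimated correlation). Adjacent loci nevertheless changed alike. The infection effects of 11806 pairs of neighbours correlated across loci with r = 0.14, against at most 0.026 in permuted orders (permutation p = 0.001, the smallest that 1000 permutations can give, and 0.0028 after adjustment over 14 statistics). Both neighbours were called higher in 181 pairs, against 93.1 on average in permuted orders (permutation p = 0.001, adjusted 0.0028). Both were called lower in 185 pairs, against 142 (permutation p = 0.002, adjusted 0.004).

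The longest stretches of neighbours called together were picked out after their values were seen. A run of 5 adjacent loci on chromosome 3 rose from a summed 173 ± 109 CPM (SD, n = 3) in untreated to 6765 ± 1368 CPM (SD, n = 2) in infected leaves, or 39.1-fold. Within the untreated group it stood at 48.8 CPM in wild type, 251 and 219 CPM in OVX6024. A run of 4 loci on chromosome 7 rose from 1.87 ± 1.85 CPM (SD, n = 3) to 334 ± 161 CPM (SD, n = 2), or 179-fold. This was 395-fold without untreated OVX6024 replicate 1 and 118-fold without infected OVX6024. Runs of 4 loci on chromosomes 1 and 11 fell from 293 ± 144 CPM to 42.5 ± 0.224 CPM and from 172 ± 12.5 CPM to 37.2 ± 3.25 CPM (SD, n = 3 untreated and 2 infected), which are falls of 6.90-fold and 4.61-fold. The longest run of rises, with 5 loci, compared with 3.29 on average in permuted orders (permutation p = 0.016, adjusted 0.0249), and the longest run of falls, with 4, with 3.62 (permutation p = 0.552, adjusted 0.594). Runs of at least 4 loci numbered 2 for rises, against 0.325 in permuted orders (permutation p = 0.045, adjusted 0.063), and 2 for falls, against 0.802 (permutation p = 0.186, adjusted 0.217). Every member kept its direction in each alternative in which it was tested, but between 0 and 4 members of these 4 runs were called when 1 library was left out. Neighbouring loci can be near-identical copies, whose reads the counting may have divided between them.

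**Figure D2:**
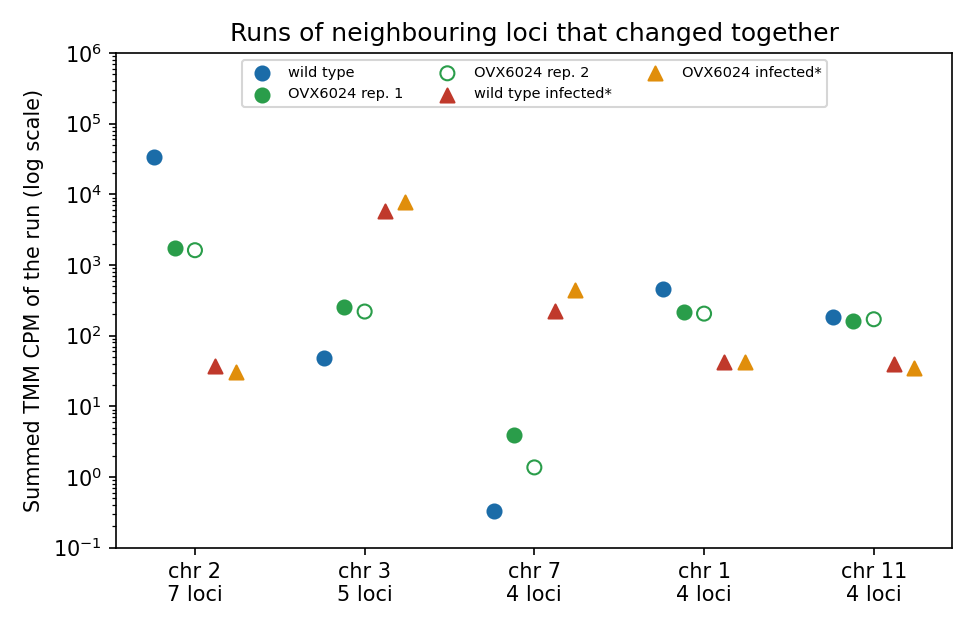
Summed TMM-scaled CPM (log axis) of each run of at least 4 adjacent loci called in the same direction, by chromosome, with 1 point per library (circles untreated, triangles infected, asterisks for conflicting genotype names). The run of 7 loci on chromosome 2 was called between the untreated genotypes (33270 CPM in wild type, 1719 and 1618 CPM in OVX6024), and the others between infected and untreated leaves.

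The comparison of untreated leaves asks what overexpression of miR6024 changed before infection. In the 2 OVX6024 libraries 338 transcripts were higher and 547 lower than in the single wild type library (edgeR quasi-likelihood test in the model of 4 groups, adjusted p between 0.0415 and 0.05). By size alone, 457 transcripts were at least 4-fold higher and 610 lower in OVX6024 replicate 1 than in wild type, and 433 and 647 in replicate 2. Between the 2 OVX6024 replicates the same rule gave 99 and 85.

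The most extensive fall lay on chromosome 2, where a run of 7 adjacent loci held 33270 CPM in untreated wild type. It held 1669 ± 71.5 CPM (SD, n = 2) in untreated OVX6024, 19.9-fold less. The longest run of falls in permuted orders had 4 loci (permutation p = 0.001, adjusted 0.0028). Each OVX6024 library alone lay 19.4-fold and 20.6-fold below wild type. In the additive model fitted with either OVX6024 library left out, which averages in the infected libraries, 0 of the 7 were called, all 7 were lower, and the median log2 effect was -3.00 and -2.71 in place of -6.44. The same loci stood at 37.2 CPM in infected wild type and 30.1 CPM in infected OVX6024. One of them, Solyc02g070990.1.1, fell from 2796 CPM in wild type to 9.89 ± 0.157 CPM (SD, n = 2) in OVX6024 (edgeR log2 fold change -8.14, SE 0.37, adjusted p = 0.0415). Solyc03g116820.2.1, on chromosome 3, had 15.9 CPM in untreated wild type and 0 counts in both untreated OVX6024 libraries, at least 169-fold lower. Transcripts higher in OVX6024 included Solyc04g078880.2.1, on chromosome 4, with 0 counts in wild type and 15.9 ± 1.50 CPM (SD, n = 2) in OVX6024, at least 64.7-fold higher. Solyc07g044970.1.1, on chromosome 7, had 0 counts and 8.75 ± 0.0989 CPM (SD, n = 2), at least 35.6-fold higher. The edgeR adjusted p was 0.0415 for each of the 3. Of 18 tested non-coding RNAs, 7 fell and 0 rose in OVX6024.

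These calls rest on 1 wild type library and the small spread of the OVX6024 pair. The model of 4 groups keeps no residual degree of freedom when 1 OVX6024 library is left out. An additive model, which estimates another quantity by averaging over infection, was fitted in its place, so the library and the model changed together. In it 3 and 2 transcripts were called without replicate 1, and 0 and 0 without replicate 2, where 1061 had an unadjusted p under 0.05 (933 without replicate 1). In those fits the log2 effect of Solyc07g044970.1.1, which stood at 277.7 CPM in infected wild type, turned to -0.77 and -0.81. That of Solyc02g070990.1.1 became -4.01 and -3.99 (edgeR adjusted p = 1.00 in both, and 0.00710 to 1.00 over its edgeR alternatives). That of Solyc04g078880.2.1 fell from 10.89 to 3.92 and 3.82 (edgeR adjusted p = 0.852 and 0.723, and 0.00816 to 0.852 over its edgeR alternatives). Solyc03g116820.2.1 went from -10.89 to -7.79 and -7.69 (edgeR adjusted p = 0.0417 and 0.0762, and 0.00816 to 0.0762 over its edgeR alternatives). The DESeq2 Wald test gave these transcripts adjusted p of 2.49e-70, 0.000133 and 2.34e-08 in the same order. Rises made up 38.2% of the calls with TMM, 50.5% with DESeq2 (784 higher and 767 lower) and 83.0% with total counts, under which 1947 were higher and 400 lower. The log2 change of the median transcript was -0.05 with TMM and 0.57 with total counts. Called loci made up 2.56% of those tested on chromosome 11 (14 higher and 17 lower of 1209) and 4.51% to 5.68% on the other chromosomes, a difference in shares that was not tested. For a shift in 1 direction, camera called no chromosome (lowest adjusted p = 0.985, and 0.890 with an estimated correlation).

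Transcripts that differed between the untreated genotypes tended to differ in the same direction between infected and untreated leaves. Of the 338 higher in OVX6024, 71 were also higher in infected leaves, against 29.9 for independent lists, and 5 were lower, against 37.2. Of the 547 lower in OVX6024, 247 were also lower in infected leaves, against 60.1, and 3 were higher, against 48.3. Both comparisons use the same untreated libraries, so part of these differences may come from them. In 20 simulations of unchanged groups no overlap arose (0 in each direction). Almost no transcript is called when nothing changes, so this does not show what the shared libraries contribute. With the infection effect fitted without untreated wild type, 115 transcripts were higher in both comparisons, against 22.2 for independent lists, and 270 were lower in both, against 44.7. In the same fit 16 were higher in OVX6024 and lower after infection, against 28.6. Another 20 were lower in OVX6024 and higher after infection, against 34.7.

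The overlap was also computed from sets with no library in common, by the rule of 4-fold and 10 CPM. The correlation used the same sets and all 18094 tested transcripts, without that rule. Over the 4 possible sets, 133 to 213 transcripts were higher in both, against 33.7 to 36.5 for independent lists, and 228 to 261 were lower in both, against 44.5 to 53.8. Those lower in OVX6024 and higher after infection numbered 16 to 28, against 46.2 to 50.7. Those higher in OVX6024 and lower after infection numbered 37 to 82, against 30.9 to 36.7. The 5 above came from edgeR calls, so the rule and the sharing of libraries changed together. The values for independent lists here are taken over all 18094 tested transcripts. Only transcripts with at least 10 CPM in the higher library could enter, so these values are too low. OVX6024 replicate 1 against wild type correlated across transcripts with infected wild type and infected OVX6024 against OVX6024 replicate 2 at r = 0.32 and 0.38. With the replicates exchanged, r was 0.31 and 0.35. With the shared libraries, r was 0.50, against 0.014 on average in 20 simulations of unchanged groups, and the covariance was 1.25 against 0.0027. These simulations gave every library the same spread, under which the contribution of the shared libraries to the covariance nearly cancels. They therefore do not show what an atypical wild type library would contribute.

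**Figure D3:**
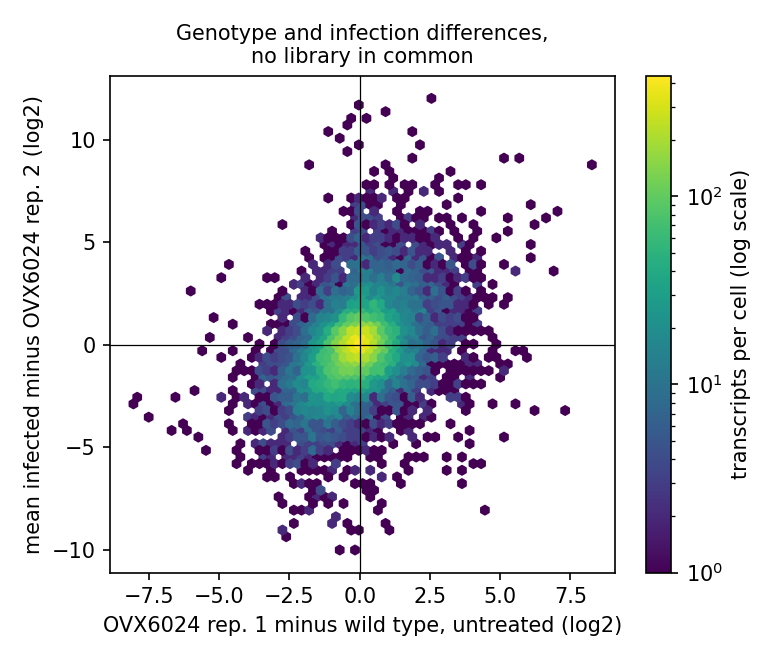
Each cell counts transcripts (log colour scale) by their log2 difference between untreated OVX6024 replicate 1 and wild type (horizontal) and between the mean of the infected libraries and OVX6024 replicate 2 (vertical), from CPM with 0.5 added. The 18094 transcripts lean along the rising diagonal (r = 0.38), although the axes share no library.

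The infected libraries were compared with each other to ask how the genotypes differed under infection. There is 1 library of each, so the difference has no replicate check. In the library named infected OVX6024, 766 transcripts were at least 4-fold higher and 473 lower than in that named infected wild type, out of 11292 with at least 10 CPM in the higher one. Exchanging the names turns these into 473 higher and 766 lower. Solyc01g090890.2.1, on chromosome 1, had 504 CPM in infected OVX6024 and 2 counts in infected wild type, a ratio of 3400 with an exact 95% counting interval of 941 to 28083. Solyc06g062550.2.1, on chromosome 6, had 281 and 0.371 CPM. The untreated OVX6024 replicates themselves lay far apart for both, at 3.78 and 27.1 CPM for the first and 3.78 and 49.5 CPM for the second. Solyc04g064770.1.1, on chromosome 4, had 71.6 CPM in infected wild type and 0 counts in infected OVX6024, at least 410-fold lower. Solyc03g116820.2.1 had 29.9 and 0.233 CPM. The last 2 transcripts also had 56.8 and 15.9 CPM in untreated wild type and at most 0.420 CPM in untreated OVX6024.

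Infected wild type had 1916 transcripts at least 4-fold higher and 2523 lower than the single untreated wild type library, out of 12830. Infected OVX6024 had 1426 and 1282 relative to the mean of the 2 untreated OVX6024 libraries, out of 12316 (totals at 10 CPM or more). With the names exchanged these became 1872 and 2281 for wild type, and 1386 and 1468 for OVX6024. The larger numbers thus went with untreated wild type as reference, whichever infected library was used. Against single untreated OVX6024 libraries, infected wild type gave 1370 to 1407 higher and 1455 to 1504 lower. Infected OVX6024 gave 1418 to 1446 and 1291 to 1320. A weaker response in OVX6024 cannot be read from these counts. Whether the infection effects differed was tested as the interaction. By edgeR, 405 transcripts had a more positive infection effect in OVX6024 than in wild type and 313 a more negative one, with adjusted p between 0.0495 and 0.05. With DESeq2 size factors in the same fit 0 and 0 were called, although 6352 had an unadjusted p under 0.05. With the names exchanged 297 and 489 were called, of which 9 and 47 were shared with the first lists.

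Over both states together, the 3 OVX6024 libraries were compared with the 2 wild type libraries. The edgeR quasi-likelihood test with infection as covariate called 0 transcripts (smallest adjusted p = 0.291, 1993 with an unadjusted p under 0.05), and 0 with the names of the infected libraries exchanged (2360). DESeq2 called 434 higher and 328 lower. Leaving out 1 library gave 561 higher and 512 lower by edgeR without untreated wild type, 227 and 375 without infected wild type, and 397 and 600 without infected OVX6024. In each of these fits a genotype contrast rests on a single wild type library, set against a single OVX6024 library where untreated wild type is left out, and the only residual degree of freedom comes from the untreated OVX6024 pair.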

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

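The test of the label conflict was chosen after the correlations between libraries had been seen. The edgeR interaction test, which compares the infection effects of the genotypes, called 405 transcripts with a more positive and 313 with a more negative effect in OVX6024. The other 3 groups had 1 library each, so the spread came from the untreated OVX6024 pair alone (1 residual degree of freedom). By edgeR with DESeq2 size factors 0 and 0 were called, with 6352 at an unadjusted p under 0.05, and the DESeq2 Wald test called 813 and 779. The calls were also 0 and 0 with the FPKM scale and with the filter of 1 CPM in 1 library. With exchanged names of the infected libraries, 9 and 47 were shared. A difference in infection effect between the genotypes is therefore not established by these calls.

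The interaction also depends on which infected library is which genotype, where the deposited names conflict. If the names of the count columns were exchanged, the difference of the infected pair might be expected to run against that of the untreated genotypes. Across transcripts the 2 differences correlated at r = 0.053, between the bounds of -0.1 and 0.1 set for a decision, so exchanged labels cannot be told apart from correct ones in this way. Of 4 transcripts with at least 5 CPM in untreated wild type and under 0.5 CPM in both untreated OVX6024 libraries, 4 were higher in the library named infected wild type and under 0.5 CPM in that named infected OVX6024, which leans towards the names of the count columns on few transcripts. Of 36 transcripts with the opposite pattern, 32 had at least 5 CPM in an infected library, and of these 19 were higher in infected OVX6024 and 13 in infected wild type.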

How the results depend on the processing

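Alternative scalings by total counts and by the FPKM scale, and the OVX6024 libraries alone, were chosen after seeing the data. Of the alternatives for counts of transcripts, 64 stayed within 1.5 times the main count and 46 did not. The cause was not tested, except that some settings used fewer libraries. For the infection effect (1599 higher, 1989 lower), the DESeq2 Wald test gave 2805 and 3246, and total counts as scale gave 1031 higher. The OVX6024 libraries alone (1 infected, 2 untreated) gave 2864 and 3387, and leaving out 1 library gave 340 to 1162 higher and 137 to 1498 lower. For the untreated genotype effect (338 and 547), the DESeq2 Wald test gave 784 higher, no filter gave 918 and 1387, total counts 1947 higher, the FPKM scale 302 lower, and leaving out 1 OVX6024 library, which also required an additive model averaging over infection, 0 to 3 higher and 0 to 2 lower. For the genotype effect over both states (0 and 0 by edgeR, 1993 at an unadjusted p under 0.05), the DESeq2 Wald test gave 434 and 328, and leaving out 1 library gave 0 to 561 and 0 to 600. For the interaction (405 and 313), 0 and 0 were called by edgeR with DESeq2 size factors (6352 at an unadjusted p under 0.05), with the filter of 1 CPM in 1 library (6507) and with the FPKM scale (6286). The DESeq2 Wald test gave 813 and 779, no filter 1516 and 1240, total counts 1789 lower, and exchanged names of the infected libraries 489 lower. Exchanging those names turned 766 higher and 473 lower in the infected pair into 473 and 766, and the log2 ratios of the named transcripts into -10.80 (Solyc01g090890.2.1), -9.12 (Solyc06g062550.2.1), 9.07 (Solyc04g064770.1.1) and 6.36 (Solyc03g116820.2.1). With 1 untreated OVX6024 library left out, the fitted effect of Solyc07g044970.1.1 (10.03) turned to -0.81 to -0.77, in a fit that also averages over infection. Among tested named transcripts, 75 alternatives kept direction and call, 8 kept direction but lost the call, and 2 reversed. Alternatives in which a transcript missed the filter are not counted. Solyc02g080840.1.1 and Solyc02g071490.2.1 were thus not tested without either infected library or in the OVX6024 libraries alone. For those named from the infected pair, which has no test, 8 kept direction and 4 reversed. No paired analysis was possible because the labels number only the 2 untreated OVX6024 samples. For the interaction no library can be left out with a test. Without 1 untreated OVX6024 library no residual degree of freedom remains. Without any other library a group is empty, and the interaction cannot be estimated. The gene list tests were not run for want of gene names. Depth limits rare transcripts, since a count of 0 allows up to 0.277 CPM in the smallest library.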

Other observations

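The tests of length, depth and abundant transcripts were set before their results were seen. The correlation and overlaps without common libraries and the description of abundance classes were chosen after seeing the data. By mean abundance over the 5 libraries, the 100 most abundant transcripts included 16 that rose and 32 that fell after infection, and 6 that rose and 18 that fell in untreated OVX6024 (edgeR adjusted p under 0.05). They took 28.5% of the counts in untreated wild type, 15.6% and 14.1% in untreated OVX6024, and 19.0% and 18.5% in the infected libraries. The next 900 transcripts held more rises than falls after infection (177 and 108), as did the 4000 after them (582 and 401). The 13094 less abundant ones showed more falls (1448) than rises (824). Of 18 non-coding RNAs tested, 1 rose and 0 fell after infection.

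The first pattern is the breadth of the difference between infected and untreated leaves (3588 transcripts). Depth is argued against, since thinning all libraries to the smallest total left 3573 calls. A length trend is argued against as well, with 3862 calls after its removal (of which 53.6% were rises, against 44.7% before). Without the 100 most abundant transcripts 3538 calls remained. TMM already trims extreme transcripts when it sets the scale, so this removal could hardly change the number. It therefore does not decide whether a few transcripts taking most of the counts shaped the calls. With total counts as scale 26.1% of the calls were rises, against 44.6% with TMM. The infection itself stays open as the biological explanation. A difference in day, handling or plants was not tested, since the labels name no batch or date. Plant age is given for the infected samples only, and no sample is labelled as mock-inoculated. Effects of age or of the applied drops therefore cannot be told apart from infection.

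The second pattern is that untreated wild type stood apart from both untreated OVX6024 libraries, and that the difference ran along the infection difference. Shared libraries as the sole source are argued against by the lowest of the 4 correlations without common libraries, 0.314. Transcript length is argued against too (977 calls after removal of its trend, against 950 on the same transcripts). Without the 100 most abundant transcripts 949 calls were made, against 885. Both fits used TMM, which trims extreme transcripts, so these numbers do not decide about abundant transcripts. With total counts as scale 83.0% of the calls were rises, against 38.2% with TMM. A hypothesis is that untreated OVX6024 leaves may already have been in a state partly like that of infected leaves. It cannot be told apart from a peculiarity of the 1 untreated wild type library, such as leaf age or time of harvest, because no second one exists in these data. Across transcripts the untreated genotype difference barely recurred in the infected pair as named (r = 0.053, Spearman rho -0.020, same sign for 47.7%). With 1 infected library per genotype and conflicting names, these values do not decide the question.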
